A study of Arabidopsis thaliana with 12 samples.

How the data were processed

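Single leaves of 6-week-old Arabidopsis plants were compared in 4 groups of 3: without and with 20 ppm isoprene, each after 24 h at 23 °C and after a further 24 h at 40 °C. Per the labels, the plants had grown under 12 h of light at 120 µmol m-2 s-1, 60% relative humidity and 23 °C by day and 20 °C by night, and isoprene or isoprene-free air was given for all 48 h. Groups and replicate numbers come from the sample labels. Nothing in the labels says whether the same plant was sampled at both temperatures. The sources used here do not give a statistical method.

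Each sample was hybridised to 1 Agilent single-colour array of 45220 spots, of which 1417 are controls. Per the file headers, the authors' scanner output was read with Feature Extraction 9.5.1.1 under protocol GE1-v5_95_Feb07, which subtracts background and removes spatial trends within an array and applies no scaling between arrays. The deposited processed signal is an intensity on a linear scale, as are the mean signal and local background used for an alternative. The authors' deposited value table also holds intensity values on a linear scale. All 12 of its columns hold the same set of values with a median of 172.5, and within every array their order equals that of the processed signal (Spearman rho of 1), so the table is a quantile normalization of the processed signal; the software used for it is not given in the sources used here. Flags for background, saturation and outliers, which are other codes of 0 or 1, were taken from the deposited scanner output per the file headers. The 43803 non-control spots hold 43603 distinct probes.

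The main values were log2 of the processed signal minus the array's own 75th percentile over non-control probes. Spots flagged as outliers were set to missing, which touched 47 genes, and saturated spots were kept. Replicate spots of a probe were averaged. Probes were kept if they were well above background on all 3 arrays of at least 1 group, which left 31592 probes. Of all probes 36695 were assigned to one of 26708 loci through the accessions and locus codes of the array design, matched to a reference gene table of assembly TAIR10.1, and 6908 were not. The file headers give an older build (ath1:Jan2004), so no coordinates are printed. Where a gene had several probes, the 1 with the highest mean over the 12 arrays stood for it, which gave 20184 genes, of which 15215 were above background on all arrays. Among 6217 genes with several kept probes, 12 had probes called in opposite directions by heat without isoprene and 9 by heat with isoprene. The 3256 kept probes without a locus were tested apart. No probe of a chloroplast-encoded locus was found on the array, so the list planned for these genes was not tested.

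Differences were tested with limma 3.58.1 (lmFit, contrasts.fit and eBayes without trend or robust option) under R 4.3.3, in one model of the 12 arrays with group as the only term. The 5 contrasts were isoprene at 23 °C, isoprene at 40 °C, heat without isoprene, heat with isoprene and the difference between the heat responses. The model had 8 residual degrees of freedom and eBayes added 5.05. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Shifts of gene lists were tested with camera in limma at its preset correlation of 0.01 and again with an estimated correlation, on the 20137 genes with a value on every array, adjusted over the lists of a contrast. The preset calls were 6, 4, 5, 9 and 4 lists in the order of the contrasts above, and with an estimated correlation 0 lists passed in any of them. The 24 lists held 340 genes: phenylpropanoid, flavonoid, plastid isoprenoid, mevalonate and carotenoid synthesis, terpene synthases, heat shock, endoplasmic reticulum folding, antioxidants, jasmonate, salicylate, abscisic acid with cold and dehydration, ethylene, light harvesting, the Calvin-Benson cycle, glucosinolates, cell wall loosening, the clock, senescence, touch, and markers of guard cells, vascular tissue and epidermis, with a list of reference genes. All 340 were on the array, 13 without a name in the reference table. Terpene synthases had 2 measured members, under the 3 required, so 23 lists were tested. The median of these 2 was -0.29 for isoprene at 23 °C, -0.22 for isoprene at 40 °C, 0.51 for heat without and 0.58 for heat with isoprene, and neither gene passed in any contrast.

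Genes named in the text follow a rule. In each contrast they are, among genes with a symbol that pass, are above background on all arrays of the higher group and whose group values do not overlap (a 10% chance for 3 against 3), up to 10 with the largest rise and 10 with the largest fall. Where fewer than 5 pass in a direction, they are the 5 with the smallest p. From each list up to 4 members with the smallest p are added, with all heat shock genes for heat and all reference genes. The groups, the model, the lists, this rule and the alternatives were chosen before the data were examined, except where the text says otherwise.

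Slide number equals replicate number: each of the 3 slides holds 1 array of every group, slide 1 was scanned in another session than slides 2 and 3, and the position on the slide equals the group, so position and group cannot be told apart. A slide block is therefore the replicate block. Whether the numbers pair the samples was checked by correlating deviations from group means between arrays of 1 number. The correlation was 0.518, 0.466 and 0.497 between the arrays at 23 °C, 0.21, 0.504 and 0.376 between those at 40 °C, 0.113, 0.276 and 0.338 between temperatures without isoprene and 0.312, 0.194 and 0.324 with isoprene. It was 0.2507, 0.2265 and 0.3019 between unfumigated arrays at 23 °C and isoprene arrays at 40 °C. Between unfumigated arrays at 40 °C and isoprene arrays at 23 °C it was 0.02865, 0.2149 and 0.2665. All but the 0.02865 of replicate 1 lie over 0.1, so the numbers were taken to pair the arrays, with the shared slide as the known link. Values with the block are given where they change a call.

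Alternatives covered normexp background correction with an offset of 50, quantile normalization, scaling to probes above background on all arrays, the authors' value table, no filter or a stricter filter on dim probes, the replicate block, a random block for the plant (correlation 0.22), fits on the groups of 1 contrast, a variance trend with robust estimation, array weights, the mean of a gene's probes, a 2-fold minimum, an adjusted p under 0.1, and leaving out each array and each replicate number. Leaving out the arrays that stood apart from their groups, and fits on the 6 arrays of one temperature with the replicate block, were added after the data had been seen.

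The steps were tested on simulated data for the 20137 genes, with 200 genes changed by known amounts, 50 of each size. At 32-fold limma recovered 86% of the changed genes for isoprene at 23 °C, 84% for isoprene at 40 °C, 74% for heat without and 82% for heat with isoprene, and 50% for the difference between heat responses. At 8-fold these shares were 26%, 38%, 40%, 42% and 8%, at 4-fold 8%, 6%, 12%, 12% and 2%, and at 2-fold 0% in each. Between 0 and 4 unchanged genes were called per contrast. In the real heat comparisons 6704 and 6505 genes passed, which eases the Benjamini-Hochberg threshold. The shares for heat therefore hold for 200 changed genes only and do not describe the real heat tests. A simulated rise of 1 (log2) in the jasmonate list for isoprene at 23 °C gave an adjusted p of 0.0751 and a rise of 2 one of 1.11e-15, with 0 other lists called. The simulated noise was independent between genes and held no slide effects. False list calls among correlated genes, as in the real lists, were therefore not tested. Tables were handled with data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.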

Results

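Leaves of Arabidopsis thaliana were profiled after 24 h at 23 °C and after a further 24 h at 40 °C, in plants that received 20 ppm isoprene throughout the 48 h and in plants that received none. Isoprene is a volatile hydrocarbon that many trees emit and that Arabidopsis does not make in large amounts. The 4 groups were leaves without isoprene at 23 °C, with isoprene at 23 °C, without isoprene at 40 °C and with isoprene at 40 °C, with 3 leaves and 3 arrays in each. No group was kept at 23 °C for 48 h, so heat below stands for 40 °C together with the further 24 h. In the isoprene groups fumigation had lasted 24 h at 23 °C and 48 h at 40 °C. The labels do not state that the 3 leaves of a group came from separate plants, so the p-values measure the spread between these samples. The 75th percentile of the signal ran from 1346 to 3548 on the arrays at 23 °C. At 40 °C it ran from 276 to 1214 on 5 arrays and was 2359 on the isoprene array of replicate 2. Between 56.8% and 79.7% of the spots of an array were well above background. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.68 for a comparison of 2 groups and 0.96 for a difference between 2 heat responses.

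The series title asks what isoprene changes in plants that were not heated. At 23 °C the circadian clock list was lower with isoprene, and the antioxidant, flavonoid, phenylpropanoid, carotenoid and touch lists were higher, in a test of each list against all other genes. Of the 10 splits of these arrays 7, the real one included, gave as many lists. The share was the same for heat without and with isoprene, so this count cannot decide whether isoprene moved the lists. The shifts are therefore not shown to come from isoprene. None of the 20184 genes passed on its own, with 181 at an unadjusted p under 0.05 in limma. That is a smaller share than chance alone would give at this threshold, so the absence of calls does not show that isoprene had no effect. Fitted on the 23 °C arrays alone with the replicate block, 1316 genes had such a p and 0 passed. Of the 16 clock genes 11 had a negative log2 fold change, and the list median was -0.75 (camera adjusted p = 0.000519; adjusted p = 0.173 with an estimated correlation). PRR5 differed by -3.27 ± 1.38 (log2, SE, n = 3 arrays per group), ELF4 by -2.93 ± 1.1 and PRR3 by -2.27 ± 0.85. Of these evening-phased repressors of the clock, PRR5 and PRR3 were highest in the unfumigated leaf of replicate 1, and ELF4 was high in the unfumigated leaves of replicates 1 (-0.15) and 2 (-0.54). The list median within slide 1 was -1.49, against -0.29 and -0.34 within slides 2 and 3. RVE1, a morning-phased factor, differed by 1.64 ± 0.90. Without the unfumigated leaf of replicate 1 the log2 fold changes were -1.138 for PRR5, -2.366 for ELF4, -1.378 for PRR3 and 0.326 for RVE1.

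**Figure D1:**
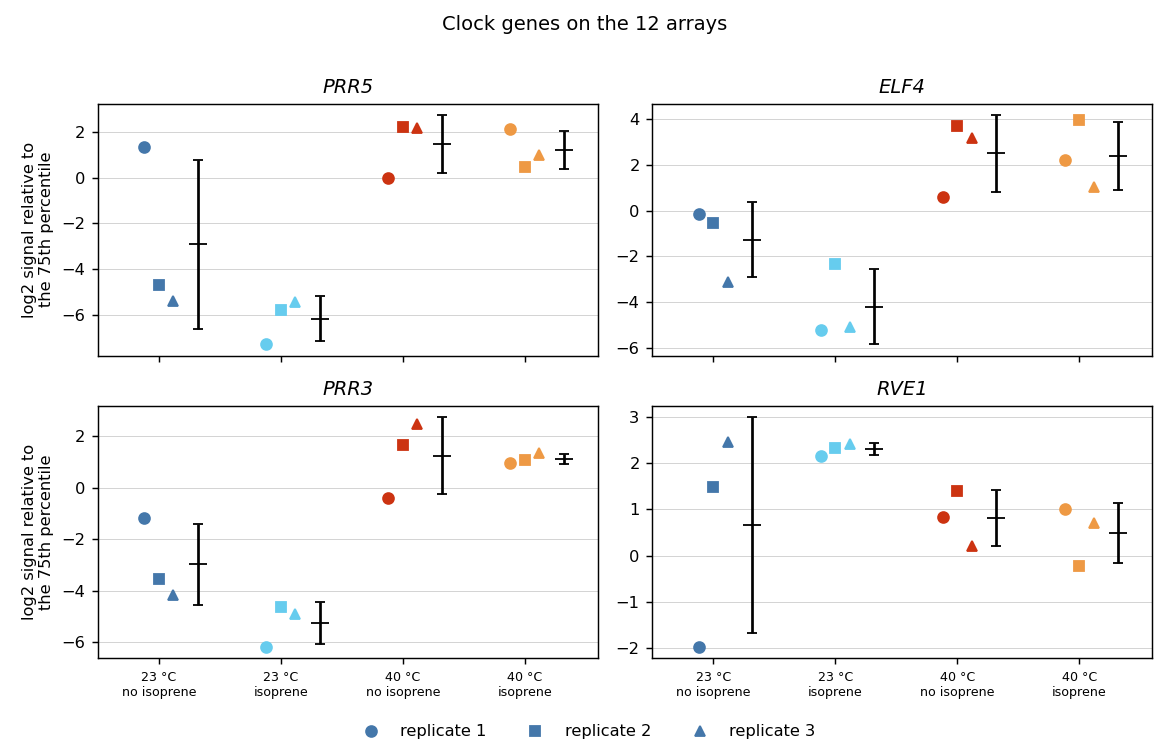
Log2 signal relative to the array's 75th percentile of 4 clock genes on the 12 arrays, with points for single leaves and a bar for the group mean ± SD (n = 3 arrays). In the unfumigated replicate 1 leaf at 23 °C PRR5 stands at 1.34, against -7.30 to -4.69 in the other 5 leaves at 23 °C.

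Antioxidant genes were positive for 13 of 17 members, with a median of 0.57 (adjusted p = 0.00044; adjusted p = 0.173 with an estimated correlation). The zinc-finger factors ZAT10 and ZAT12, which respond to oxidative stress, differed by 2.57 ± 0.91 and 2.21 ± 0.79. Within slides 1, 2 and 3 the antioxidant median was 0.58, 0.54 and -0.01. Flavonoid genes were positive for 11 of 12 members, with a median of 0.63 (adjusted p = 0.000519; adjusted p = 0.173 with an estimated correlation). TT4, the chalcone synthase that opens flavonoid synthesis, differed by 2.71 ± 1.16 and F3H by 2.28 ± 1.19. The flavonoid median was 2.2 within slide 1, 0.36 within slide 2 and 0.24 within slide 3. Phenylpropanoid and lignin genes were positive for 15 of 17 members (median 0.62, adjusted p = 0.00249; adjusted p = 0.576 with an estimated correlation). Among them, the cinnamate hydroxylase C4H differed by 1.27 ± 0.69 and the ammonia-lyase PAL4 by 1.14 ± 0.94. Their medians within the slides were 1.37, 0.02 and 0.39. Carotenoid genes were positive for 10 of 12 members (median 0.40, adjusted p = 0.00426; adjusted p = 0.576 with an estimated correlation), with medians of 0.62, 0.52 and 0.14 within the slides. The carotene hydroxylases BETA-OHASE1 and BETA-OHASE2 differed by 1.41 ± 0.78 and 1.78 ± 0.81. All 5 touch and wounding genes were positive (median 0.89, adjusted p = 0.00807; adjusted p = 0.576 with an estimated correlation). Their medians within the slides were 1.21, -0.28 and 1.76, WRKY40 differed by 2.25 ± 1.32 and the calmodulin-like TCH2 by 1.11 ± 0.73.

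The other 17 lists tested at 23 °C did not pass. The closest was the heat shock list, with a median of -0.12 over 30 genes (adjusted p = 0.0598) and medians of 1.59, -0.38 and -1.48 within the slides. Salicylate genes had a median of 0.34 (adjusted p = 0.152) and the plastid isoprenoid pathway, which supplies the precursor of isoprene in emitting species, one of 0.27 (adjusted p = 0.224), with DXR at 0.35 ± 0.61 and HDR at 0.49 ± 0.61. Calvin-Benson cycle genes were positive for all 9 members (median 0.33, adjusted p = 0.169). The median and the test differed in sign for the ethylene list (0.08, tested down, adjusted p = 0.326), the senescence list (0.17, tested down, adjusted p = 0.196) and the glucosinolate list (0.09, tested down, adjusted p = 0.976). Reference genes had a median of 0.05, with 0.35 ± 0.62 for ACT2 and -0.07 ± 0.44 for PP2AA3.

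The single genes with the smallest p at 23 °C were higher for ARR15, NAC066, MES16, NCED5 and ECP63 and lower for NAC047, PLS, RTFL21, MRD1 and UGT85A4, all with an adjusted p of 1. ARR15 (AT1G74890), a response regulator that is induced by cytokinin and limits its signalling, differed by 4.07 ± 1.09. NCED5 (AT1G30100), an enzyme of abscisic acid synthesis, differed by 3.29 ± 0.97, and the transcription factor NAC047 (AT3G04070) by -2.43 ± 0.57. ECP63 was above background on none of the unfumigated arrays and at least 4.05-fold higher with isoprene. In the dimmer group NAC066, NCED5, NAC047 and PLS were above background on 1 of 3 arrays and RTFL21 and PRR5 on 2, so their fold changes rest partly on signals near the floor. In every list of the 24, 0 genes passed when adjusted over the list alone. With array weights limma called 6 genes, 2 higher and 4 lower, NAC047 and PLS among them (adjusted p = 0.0464 for both).

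Of the 6 list calls, 2 ended when the unfumigated replicate 1 array was left out: flavonoid (adjusted p = 0.119) and touch (adjusted p = 0.128). The touch call also ended without the unfumigated array of replicate 3 (0.0758) and without the isoprene array of replicate 3 (0.498), the phenylpropanoid call without the isoprene array of replicate 1 (0.655), and the carotenoid call without the unfumigated array of replicate 2 (0.0754). With normexp background correction flavonoid genes alone passed, and the adjusted p was 0.432 for antioxidant, 0.432 for phenylpropanoid, 0.71 for carotenoid, 0.114 for clock and 0.259 for touch genes. The unfumigated arrays of replicates 1 and 3 stood apart from the other leaves at 23 °C, the former in clock genes and the latter in some heat transcripts only. Leaving out both, which was chosen after this was seen, sets 1 unfumigated array against 3, with its spread taken from the other groups. No calls are drawn from that comparison.

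**Figure D2:**
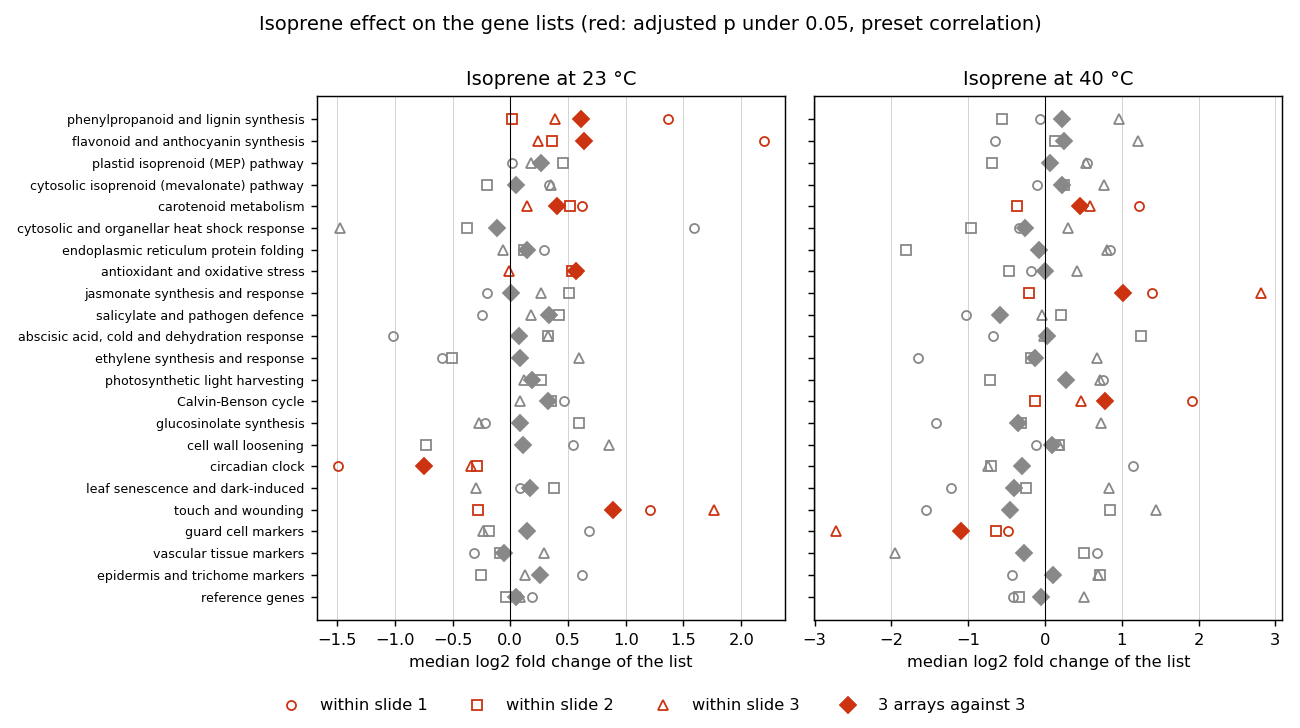
Median log2 fold change with isoprene of each gene list at 23 °C and 40 °C, with filled diamonds for 3 arrays against 3 and open symbols for the single pairs of arrays within slides 1, 2 and 3. Jasmonate genes at 40 °C have a median of 1.01, with 1.40, -0.21 and 2.82 within the slides.

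In heated leaves the question was whether isoprene changed transcript levels at 40 °C. The list test called 4 lists there, and 5 of the 10 splits of these arrays, the real one included, gave as many. Jasmonate genes had a positive log2 fold change for 21 of 22 members, none of which passed, with a median of 1.01 (adjusted p = 3.61e-06; adjusted p = 0.737 with an estimated correlation). VSP2 and VSP1, storage proteins that accumulate with jasmonate, differed by 2.45 ± 1.35 and 2.34 ± 1.30 (log2, SE, n = 3 arrays per group), and the lipoxygenases LOX3 and LOX4, which make jasmonate precursors, by 1.78 ± 0.85 and 2.54 ± 1.27. The list median was 1.40, -0.21 and 2.82 within slides 1, 2 and 3. Guard cell markers had a negative log2 fold change for 7 of 8 members, with a median of -1.1 (adjusted p = 0.000313; adjusted p = 0.737 with an estimated correlation) and medians of -0.49, -0.64 and -2.73 within the slides. The anion channel SLAC1, which closes stomata, differed by -1.89 ± 0.58 and the kinase HT1 by -1.80 ± 0.55, and both passed when adjusted over the list alone.

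The Calvin-Benson cycle list was positive for all 9 members (median 0.78, adjusted p = 0.00479; adjusted p = 0.792 with an estimated correlation). Its medians within the slides were 1.91, -0.12 and 0.47, and RBCS1A, a small subunit of Rubisco, and GAPB differed by 1.03 ± 0.79 and 0.93 ± 0.74. Carotenoid genes were positive for 10 of 12 members (median 0.46, adjusted p = 0.00677; adjusted p = 0.737 with an estimated correlation), with 1.22, -0.36 and 0.59 within the slides. Their hydroxylases BETA-OHASE1 and BETA-OHASE2 differed by 2.11 ± 0.78 and 2.24 ± 0.81. Heat shock genes were negative for 23 of 30 members at 40 °C, with a median of -0.26 (adjusted p = 0.596). Mevalonate genes had a median of 0.22 (adjusted p = 0.0754), light harvesting genes one of 0.27 (adjusted p = 0.144) and salicylate genes one of -0.59 (adjusted p = 0.144). Of the senescence list, with a median of -0.40 (adjusted p = 0.224), SAG13 passed when adjusted over the list alone, at -3.10 ± 0.80. The median and the test differed in sign for endoplasmic reticulum folding genes (-0.07, adjusted p = 0.876), antioxidant genes (0.00, adjusted p = 0.876) and reference genes (-0.05, adjusted p = 0.928), among them ACT2 at 0.22 ± 0.62 and PP2AA3 at -0.41 ± 0.44.

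No single gene passed at 40 °C in limma, where 684 of 20184 had an unadjusted p under 0.05 and the smallest adjusted p was 0.716. The 684 are again a smaller share than chance alone would give at that threshold, in a model that leaves the slide out. With the replicate block, which is the slide, 1111 genes had such a p. On the 40 °C arrays alone with the block it was 673, and no gene passed in either fit. CYP94B3 (AT3G48520) and CYP94B1 (AT5G63450), which oxidise the active jasmonate conjugate, differed by 3.44 ± 0.58 and 4.07 ± 0.97, and the glycosyltransferase UGT76E12 (AT3G46660) by 4.09 ± 0.80. ZW9 and the glutathione transferase GSTU6 were 3.18 ± 0.65 and 3.30 ± 0.74 higher. In the other direction, the phi-class glutathione transferases GSTF7 (AT1G02920) and GSTF2 differed by -4.76 ± 0.95 and -3.38 ± 0.71, and the methionine sulfoxide reductase MSRB8 by -4.56 ± 0.97. WRKY50 and SCPL15 were at least 2.98-fold and 5.45-fold lower with isoprene, where neither was well above background. In the dimmer group UGT76E12 and MSRB8 were above background on 1 of 3 arrays and LOX4 and SAG13 on 2. A bound of this kind compares the brighter group with the detection limit of each array of the dimmer group, or with the probe's own signal where that was higher.

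At 40 °C the unfumigated array of replicate 1 and the isoprene array of replicate 2 correlated least with the other heated arrays. Without both, an alternative chosen after this was seen, 179 genes passed, 83 higher and 96 lower, including CYP94B3 (adjusted p = 0.0334) and UGT76E12 (0.0338), and 9 lists passed. Among these, with the adjusted p at an estimated correlation after each, were jasmonate (2.68e-10; 0.3) and light harvesting genes (6.6e-06; 0.485), which were higher, and guard cell (0.000122; 0.485) and vascular markers (0.0144; 0.485), which were lower. With an estimated correlation 0 lists passed there. The isoprene arrays left were those of replicates 1 and 3, and the unfumigated arrays left those of replicates 2 and 3. Isoprene is thus partly slide 1 against slide 2 in this alternative. Its genes and lists are not shown to come from isoprene. The number of lists was 10 without the isoprene array of replicate 2 alone and 2 without the unfumigated array of replicate 1, the isoprene array of replicate 1 or the isoprene array of replicate 3. The Calvin-Benson and carotenoid calls ended in each of those last 3 cases and without the unfumigated array of replicate 2 (Calvin-Benson adjusted p between 0.167 and 0.317; carotenoid between 0.0504 and 0.317). The guard cell call ended without the unfumigated array of replicate 3 (0.0528), and both the guard cell and jasmonate calls ended without all arrays of replicate 3 (0.291 for both). The carotenoid adjusted p was 0.0554 with quantile normalization and 0.0582 on the authors' value table.

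Across genes, which are not independent replicates, the isoprene effects at 23 °C and 40 °C correlated with a Pearson r of 0.27 and a Spearman rho of 0.284 over 20184 genes. Within slides 1, 2 and 3 the Pearson r was 0.209, 0.00707 and 0.149. With normexp background correction it was -0.0745.

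From 23 °C to the end of the further 24 h at 40 °C, without isoprene, 3281 genes rose and 3423 fell of 20184. Temperature and the added time cannot be told apart in these changes. All 30 heat shock genes rose, with a median log2 fold change of 8.54, and the heat stress factor HSFA3 (AT5G03720) rose by 8.74 ± 0.50 (log2, SE, n = 3 arrays per group, adjusted p = 3.5e-06). HSFA2 rose by 8.36 ± 1.62 and HSP101, the disaggregase needed for acquired thermotolerance, by 7.15 ± 1.08. The plastid chaperone HSP21 rose by 13.61 ± 2.06, but at 23 °C it was above background on 1 of 3 arrays only, that of replicate 3, where it stood at 1.115 against -9.01 and -9.36. HSP23.6-MITO rose by 13.59 ± 1.40. HSP17.6C rose by 13.46 ± 1.64, HSP22.0 by 13.42 ± 1.74, HSP17.6II by 11.76 ± 1.29 and HSP17.6A by 11.66 ± 1.19, while HSP90.1, HSP70 and the plastid disaggregase CLPB3 rose by 6.52 ± 0.93, 6.16 ± 1.01 and 2.84 ± 0.46. Other large rises were those of HSP17.4 (12.265 ± 1.02), APX2 (11.69 ± 1.47), which removes peroxide, DREB2C (12.34 ± 1.03), a factor of drought and heat responses, and of SRO3, which was at least 958-fold higher. At 23 °C HSP22.0, HSP17.6II and APX2 were likewise above background on 1 array and HSP23.6-MITO, HSP17.6A and DREB2C on 2, so the sizes of these rises are uncertain. The list test gave an adjusted p of 5.7e-23 (adjusted p = 0.285 with an estimated correlation) and medians of 10.38, 7.74 and 6.53 within slides 1, 2 and 3. For heat without and with isoprene alike, 7 of the 10 splits of the arrays, the real one included, gave as many lists.

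**Figure D3:**
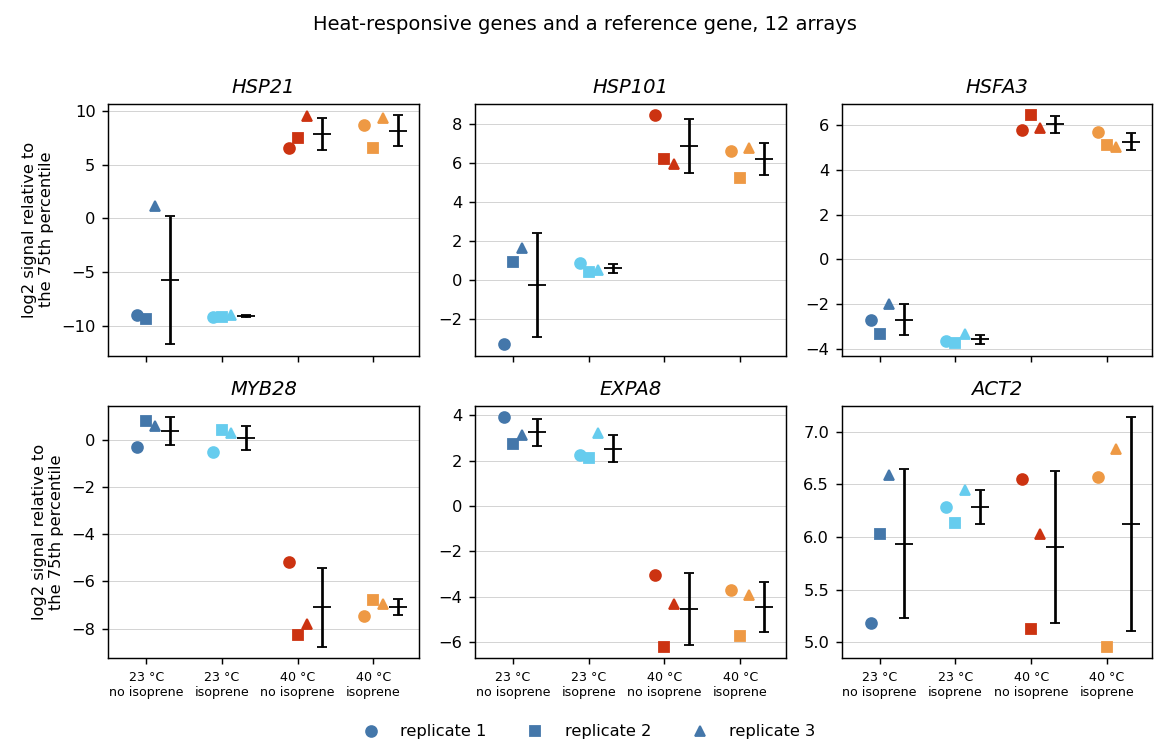
Log2 signal relative to the array's 75th percentile of 3 heat shock genes, 2 genes that fell and the reference gene ACT2 on the 12 arrays, with points for single leaves and a bar for the group mean ± SD (n = 3 arrays). HSFA3 was higher by 8.74 without and 8.85 with isoprene, and MYB28 differed by -7.44 and -7.14.

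All 13 genes of protein folding in the endoplasmic reticulum rose, with a median of 3.53 (adjusted p = 4.47e-07; adjusted p = 0.345 with an estimated correlation) and 3.51, 3.66 and 4.22 within the slides. TMS1, a co-chaperone, rose by 6.36 ± 0.86, BIP2 by 5.32 ± 0.77, BIP1 by 4.68 ± 0.72 and calnexin CNX1 by 4.66 ± 0.75. Of 17 antioxidant genes 7 rose and 10 did not pass (median 1.21, adjusted p = 0.00884; adjusted p = 0.345 with an estimated correlation), with ZAT12 at 6.85 ± 0.79, ZAT10 at 4.45 ± 0.91, the alternative oxidase AOX1A at 3.41 ± 0.74 and the glutathione transferase GSTU19 at 3.43 ± 0.71. Their medians within the slides were 1.29, 1.44 and 0.89. That list did not pass with quantile normalization (0.0886) or on the authors' value table (0.121). Adjusted over the list alone, 30 heat shock, 13 endoplasmic reticulum and 8 antioxidant genes rose.

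Glucosinolates are defence compounds of this plant family, and 9 of their 15 genes fell while 6 did not pass (median -3.04, adjusted p = 1.03e-05; adjusted p = 0.285 with an estimated correlation). The regulator of aliphatic glucosinolates MYB28 (AT5G61420) fell by 7.44 ± 0.73, and MYB34, which controls the indolic branch, fell by 6.235 ± 0.67. The cytochromes CYP79F1 and CYP83B1 fell by 4.43 ± 0.66 and 4.33 ± 0.54. The medians within the slides were -2.62, -3.75 and -3.62. Of 18 cell wall loosening genes 9 fell (median -2.29, adjusted p = 0.00314; adjusted p = 0.467 with an estimated correlation), including the expansins EXPA8 (AT2G40610), which fell by 7.77 ± 0.79, EXPA1, which fell by 6.04 ± 0.94, and EXPA5, which fell by 3.85 ± 0.74. Their medians within the slides were -1.81, -3.33 and -1.36. Adjusted over the list alone, 10 glucosinolate and 9 cell wall genes fell. Large falls outside the lists were those of the germin-like GER1, which fell by 7.85 ± 0.89, NAC1 (7.68 ± 0.95 lower on the log2 scale), DRT100, which fell by 7.15 ± 0.94, and SPL2, which fell by 7.08 ± 0.91. KCS1, an enzyme of very long chain fatty acids, fell by 7.18 ± 1.23, ACD6 by 7.05 ± 0.89 and BBX19 by 7.02 ± 1.245, and NIG1 was at least 55.2-fold lower. At 40 °C MYB28, NAC1, SPL2 and BBX19 were above background on 1 of 3 arrays.

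Lists that did not pass in heat without isoprene held genes that did. Of 16 clock genes 6 rose and 2 fell (adjusted p = 0.112), with LUX up by 5.27 ± 0.88, PRR3 up by 4.22 ± 0.85 and FKF1 up by 3.28 ± 0.51, and PRR9 differing by -3.74 ± 0.83. The clock median was -0.14, 3.30 and 3.00 within slides 1, 2 and 3, and slide 1 holds the unfumigated 23 °C leaf with high PRR5. Of 17 phenylpropanoid genes 1 rose and 6 fell (adjusted p = 0.145), of 15 salicylate genes 2 rose and 6 fell (adjusted p = 0.188), and of 18 abscisic acid, cold and dehydration genes 6 rose and 2 fell (adjusted p = 0.186). WRKY18 rose by 3.10 ± 0.53 and the cold- and dehydration-induced RD29A, KIN1 and COR47 by 4.42 ± 0.98, 4.01 ± 0.84 and 3.72 ± 0.75, while FAH1 fell by 3.15 ± 0.61. Calls of 4 further members depended on the scaling or on single arrays: PR1 (1.93 ± 0.58; adjusted p = 0.0563 with quantile normalization), WRKY54 (-3.40 ± 0.99; 0.0784 without the 23 °C array of replicate 1), PAL4 (-3.29 ± 0.94; 0.473 with normexp) and CAD5 (2.06 ± 0.51; 0.118 with quantile normalization). Of 11 epidermis and trichome markers 1 rose and 5 fell (adjusted p = 0.0607). With slide, which equals replicate number here, as a block this list passed (0.0477; adjusted p = 0.26 with block and estimated correlation), and GL1, a trichome regulator, rose by 7.63 ± 1.13 from a level above background on 1 of 3 arrays, while the wax gene CER2 fell by 3.38 ± 0.79 and ATML1 by 2.85 ± 0.63. The remaining lists held at most 3 genes that passed: jasmonate 2 up and 1 down of 22 (adjusted p = 0.292), flavonoid 2 down of 12 (0.188), carotenoid 2 down of 12 (0.299), plastid isoprenoid 1 up of 10 (0.297), mevalonate 1 down of 11 (0.253), ethylene 1 down of 10 (0.859), light harvesting 1 down of 14 (0.987), senescence 1 down of 13 (0.935), touch 1 down of 5 (0.987) and vascular markers 1 down of 10 (0.188). None of 9 Calvin-Benson genes (0.935; median 0.07, tested down) and none of 8 guard cell markers (0.935) passed. For ethylene, light harvesting and senescence genes the median (0.44, 0.26 and -0.11) or the mean (-0.42, -0.20 and -0.09) differed in sign from the test.

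The reference genes GAPC1 and YLS8 rose by 1.99 ± 0.58 and 1.76 ± 0.44 without isoprene, and neither call held with quantile normalization (adjusted p = 0.0526 and 0.24) or on the authors' value table (0.125 and 0.307). The GAPC1 call also ended without the 23 °C array of replicate 2 (0.0656), the 23 °C array of replicate 3 (0.0523) or the 40 °C array of replicate 3 (0.0751). ACT2 and PP2AA3 stood at -0.03 ± 0.62 and -0.30 ± 0.44, and the list of 11 reference genes had a median of 0.81 (adjusted p = 0.188).

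Of the 6704 genes called without isoprene 98.2% had the same sign within all 3 slides, a share that calling them on the same arrays favours. With the slide block 8388 were called. Rises made up 48.9% of the calls. They made up 31.2% (2197 of 7047) when arrays were scaled to probes above background on all arrays and 59.1% (2211 of 3741) with normexp. The median over all genes moved with the scaling, from -0.07 to -0.63 and 0.42 for these settings, to -0.24 with quantile normalization and to 0.53 without the filter on dim probes, so the changes are relative to the array's 75th percentile. The number of genes fell to 4317 without the 23 °C array of replicate 2 and to 1604 without all arrays of replicate 3, and without the unfumigated 23 °C arrays of replicates 1 and 3 it was 1567, with 1 unheated array left and the spread taken from the other groups. It was 10372 without the pair of heated arrays that stood apart.

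With isoprene, heat raised 2963 genes and lowered 3542 of 20184. All 30 heat shock genes rose again, with a median of 8.07 (adjusted p = 1.06e-23; adjusted p = 0.225 with an estimated correlation) and medians of 8.25, 7.50 and 8.24 within the slides. HSP21 was at least 45200-fold and HSP23.6-MITO at least 24700-fold higher, since neither was well above background with isoprene at 23 °C, and HSP22.0, APX2 and DREB2C were at least 24600-fold, 6380-fold and 3480-fold higher. For 4 of the 30 genes only such a bound could be given, and with these at their bounds the median was also 8.07. HSFA3 rose by 8.85 ± 0.50 (log2, SE, n = 3 arrays per group, adjusted p = 2.97e-06) and HSP101 by 5.63 ± 1.08. HSP17.6C rose by 15.43 ± 1.64, HSP17.4 by 13.54 ± 1.02, HSP17.6A by 13.23 ± 1.19, HSP17.6II by 12.57 ± 1.29 and HSP18.2 by 12.15 ± 1.0. At 23 °C HSP17.6A was above background on 1 of 3 arrays and HSP17.6C, HSP17.4 and HSP17.6II on 2. HSFA2 and CLPB3 rose by 6.01 ± 1.62 and 1.84 ± 0.46, the first not without the 40 °C array of replicate 1 (adjusted p = 0.0524) or 3 (0.0537) and the second not with quantile normalization (0.094). Of 13 endoplasmic reticulum folding genes 12 rose (median 3.76, adjusted p = 3.22e-07; adjusted p = 0.322 with an estimated correlation; within slides 4.36, 1.74 and 5.38), TMS1 by 6.14 ± 0.86 and BIP2 by 4.50 ± 0.77.

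Glucosinolate genes fell in 10 of 15 cases (median -3.43, adjusted p = 2.59e-06; adjusted p = 0.225 with an estimated correlation), MYB28 by 7.14 ± 0.73 and the transporter gene BAT5 (AT4G12030), whose product carries chain-elongation intermediates, by 7.03 ± 0.90. CYP79F1 fell by 4.96 ± 0.66 and CYP83A1 by 4.30 ± 0.52. Cell wall loosening genes fell in 8 of 18 cases (median -1.88, adjusted p = 0.00583; adjusted p = 0.461 with an estimated correlation), EXPA8 by 6.98 ± 0.79 and EXPA5 by 5.50 ± 0.74. The medians within the slides were -3.09, -4.50 and -3.56 for glucosinolate and -3.04, -1.33 and -2.69 for cell wall genes. Adjusted over the list alone, 12 glucosinolate and 8 cell wall genes fell. Outside the lists, DRT100 fell by 7.94 ± 0.94, the flowering-related COL2 by 7.87 ± 1.0, the aspartate kinase AK3 by 7.56 ± 0.96 and ACD6, a regulator of defence and cell death, by 7.19 ± 0.89. NIG1 fell by 7.78 ± 0.86 and BGLU33 fell by 7.395 ± 0.85, and RR16, a relative of ARR15, was at least 90.0-fold lower at 40 °C. There MYB28, NIG1 and BGLU33 were above background on 1 of 3 arrays and DRT100 and BAT5 on 2.

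Of 16 clock genes 8 rose and 3 fell with isoprene (median 2.54, adjusted p = 0.0305; adjusted p = 0.322 with an estimated correlation; within slides 2.1, 2.85 and 1.74). ELF4 rose by 6.60 ± 1.1, PRR3 by 6.37 ± 0.85 and LUX by 6.23 ± 0.88, while PRR9 fell by 4.71 ± 0.83. Jasmonate genes rose in 6 of 22 cases (median 2.1, adjusted p = 0.0208; adjusted p = 0.593 with an estimated correlation; within slides 3.38, -0.05 and 2.48). The repressors JAZ10 and JAZ2, which jasmonate induces, rose by 3.82 ± 0.82 and 2.68 ± 0.58. LOX3 and JAZ7 rose by 3.00 ± 0.85 and 4.65 ± 1.48, and both calls ended when any of 4 single arrays was left out, the 40 °C array of replicate 1 among them (adjusted p = 0.0625 and 0.126). Of 15 salicylate genes 9 fell and 2 rose (median -3.13, adjusted p = 0.0305; adjusted p = 0.322 with an estimated correlation; within slides -2.76, -2.56 and -1.69). PBS3, an enzyme of salicylate synthesis, fell by 3.99 ± 0.80, PR5 by 3.37 ± 0.69 and WRKY54 by 4.58 ± 0.99, while WRKY18 rose by 3.51 ± 0.53. At 40 °C WRKY54 was above background on 1 of 3 arrays and PBS3 on 2, as were PAL4 and PRR9. Of 17 phenylpropanoid genes 7 fell and 1, CAD5, rose by 2.96 ± 0.51 (median -2.63, adjusted p = 0.0305; adjusted p = 0.589 with an estimated correlation; within slides -2.25, -2.94 and -2.34). FAH1, a hydroxylase of lignin and sinapate synthesis, fell by 3.40 ± 0.61 and PAL4 by 4.53 ± 0.94. Flavonoid genes fell in 3 of 12 cases (median -2.14, adjusted p = 0.0387; adjusted p = 0.413 with an estimated correlation; within slides -2.13, -2.35 and -1.73), the glycosyltransferase UGT78D1 by 3.00 ± 0.62. The calls of F3H, which fell by 3.89 ± 1.19, and TT4, which fell by 3.285 ± 1.16, ended without the 23 °C array of replicate 1 (adjusted p = 0.104 and 0.183). Adjusted over the list alone, 9 clock and 6 jasmonate genes rose, and 9 salicylate, 8 phenylpropanoid and 2 flavonoid genes fell.

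Among lists that did not pass with isoprene, 4 of 17 antioxidant genes rose (adjusted p = 0.0585), 5 abscisic acid, cold and dehydration genes rose and 1 fell of 18 (0.0936), with RD29A at 5.16 ± 0.98 and KIN1 at 3.97 ± 0.84, and 4 of 10 vascular markers fell (0.0585), among them the phloem gene SEOR1, which fell by 3.35 ± 0.66. Of 11 epidermis and trichome markers 1 rose and 4 fell (0.0532; 0.0419 with the slide block; 0.325 with block and estimated correlation). GL1 was at least 28.5-fold higher, a call that ended with normexp (adjusted p = 0.363), and CER2 fell by 3.01 ± 0.79, a call that ended without the 23 °C array of replicate 1 (0.0538). Plastid isoprenoid (0.309), mevalonate (0.548), Calvin-Benson (0.639) and guard cell genes (0.182) had no member that passed. Single members passed among ethylene (1 down, 0.885), light harvesting (1 down, 0.719), touch (1 down, 0.46) and senescence genes (1 up, 0.95), and 2 carotenoid genes fell (0.46). GAPC1 and YLS8 rose by 1.98 ± 0.58 and 1.79 ± 0.44, while ACT2 and PP2AA3 stood at -0.17 ± 0.62 and -0.635 ± 0.44 (list adjusted p = 0.208). The GAPC1 call ended when any of 4 single arrays was left out (adjusted p between 0.0689 and 0.0842). On the authors' value table neither call held (0.0638 and 0.168), and with quantile normalization that of YLS8 did not (0.128).

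Of the 6505 genes called with isoprene 98.7% had the same sign within all 3 slides, a share that is likewise favoured by calling them on these arrays. With the slide block 8188 were called. Rises made up 45.6% of the calls, and 30.4% (2093 of 6894) when arrays were scaled to probes above background on all arrays. They made up 50.61% with normexp, 54.08% without the filter on dim probes and 53.99% with the stricter filter. The count was 4270 without the 40 °C array of replicate 1, 4323 without that of replicate 3, 4081 without the 23 °C array of replicate 3 and 1325 without all arrays of replicate 3; it was 10499 without the pair of heated arrays that stood apart. Without the 23 °C array of replicate 1 only 5 lists passed, since the clock (adjusted p = 0.0602), flavonoid (0.0852), phenylpropanoid (0.0852) and jasmonate (0.0745) calls ended. Without the 40 °C array of replicate 2 the clock (0.0537), flavonoid (0.0962), phenylpropanoid (0.224) and salicylate (0.063) calls ended, and without that of replicate 3 the jasmonate call did (0.056). With quantile normalization the flavonoid (0.0565) and salicylate (0.0518) calls ended, as they did on the authors' value table (0.0619 and 0.0605), and the flavonoid call also ended when arrays were scaled to probes above background on all arrays (0.0565). Without the filter on dim probes the clock (0.106) and jasmonate (0.0689) calls ended, and without the pair of heated arrays that stood apart the clock (0.0574), flavonoid (0.109) and phenylpropanoid (0.203) calls did.

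The heat responses without and with isoprene were then set against each other. They share no array but use the same 3 slides, and deviations of arrays on the same slide were correlated. The correlation and overlap below are therefore not those of independent estimates. Their log2 fold changes correlated across 20184 genes with a Pearson r of 0.939 and a Spearman rho of 0.936, and within slides 1, 2 and 3 the Pearson r was 0.74, 0.832 and 0.889. Of the called genes 2543 rose in both and 2728 fell in both, where independent lists would share 481.65 and 600.69, and 0 genes were called in opposite directions. No gene passed the test of the difference itself in limma, with 232 genes at an unadjusted p under 0.05, so a gene called in 1 of the heat comparisons alone is not shown to differ. The 232 are likewise a smaller share than chance alone would give at that threshold, in a model that leaves the slide out. With the replicate block, which is the slide, 409 genes had such a p and 0 passed.

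Of the 23 lists 4 passed the list test for the difference between the heat responses. In 69 of 100 relabellings of isoprene within temperature as many lists passed. Counts of lists did not set the real split apart for heat either, so this count cannot decide. The differences are not shown to come from isoprene. Jasmonate genes had a positive difference for 17 of 22 members, with a median difference of 0.99 (adjusted p = 0.000336; adjusted p = 0.674 with an estimated correlation) and 0.75, -1.06 and 2.56 within the slides, with VSP1 at 2.52 ± 1.84 and VSP2 at 2.62 ± 1.91. Guard cell markers had a negative difference for all 8 members (median -1.24, adjusted p = 0.000336; adjusted p = 0.503 with an estimated correlation; within slides -0.73, -0.39 and -2.32), with HT1 at -1.715 ± 0.77 and SLAC1 at -1.47 ± 0.815. Salicylate genes had a negative difference for 13 of 15 members (median -0.93, adjusted p = 0.0114; adjusted p = 0.503 with an estimated correlation; within slides -1.07, -0.67 and -0.42), with PR5 at -2.56 ± 0.97. Antioxidant genes had a negative difference for 14 of 17 members (median -0.36, adjusted p = 0.0114; adjusted p = 0.58 with an estimated correlation; within slides 0.04, -1.42 and 0.38), with ZAT12 at -3.48 ± 1.12 and ZAT10 at -3.37 ± 1.28. The antioxidant call ended with normexp (adjusted p = 0.779). Touch genes had a median of -1.48 (adjusted p = 0.116), the clock list one of 0.29 (0.147), and heat shock genes one of -0.04 with 15 positive and 15 negative members (0.671).

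Single arrays moved these 4 calls. Without the unfumigated 40 °C array of replicate 1 the antioxidant (adjusted p = 0.121) and salicylate (0.56) calls ended, which left 2 lists. Without that of replicate 3 the antioxidant (0.113), guard cell (0.0569) and jasmonate (0.123) calls ended. There 2 lists passed as well, salicylate and a list not among the 4. The isoprene array of replicate 2 at 40 °C carried the antioxidant (0.649 without it) and salicylate (0.0713) calls, that of replicate 1 the jasmonate (0.0886) and salicylate (0.078) calls, and that of replicate 3 the jasmonate call (0.116). At 23 °C the antioxidant call ended without the isoprene array of replicate 1 (0.0641) or the unfumigated array of replicate 2 (0.0503), and the salicylate call without the isoprene array of replicate 2 (0.0533) or the unfumigated array of replicate 3 (0.0591). Without the unfumigated array of replicate 2 at 23 °C 7 lists passed, as many as without the unfumigated array of replicate 2 at 40 °C.

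The single genes with the smallest p for this difference were lower for WRKY50, MSRB8, NAC036, BCS1 and UMAMIT27 and higher for UGT76E12, CYP94B3, CYP94B1, ZW9 and TTL4, all with an adjusted p of 1. WRKY50 (AT5G26170), a factor of defence signalling, differed by -4.12 ± 0.78, and UGT76E12 by 4.46 ± 1.13. CYP94B3, which inactivates the jasmonate conjugate, differed by 3.56 ± 0.82. WRKY50 was above background on none of the isoprene arrays at 40 °C and MSRB8 and UMAMIT27 on 1 of them, and UGT76E12 was above background on no array at 23 °C, so these values rest on signals near the floor.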

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

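In this part the test on dawn-phased genes, the test of signal brightness and the test of the correlation over 100 relabellings were set before their results were seen; the other tests, including those on splits of the arrays and on labellings that part every slide, were chosen afterwards.

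For 10 named genes every replicate moved one way with isoprene at 23 °C and the other way at 40 °C. All named genes were searched for this, and how many would do so by chance was not tested. The mean effect within slides went from 1.25 to -2.87 for the defence factor WRKY50 (difference -4.12), from 3.28 to -0.88 for NCED5 (-4.16), from 0.97 to -2.86 for NAC036 (-3.83), from 1.95 to -1.45 for BCS1 (-3.40) and from 0.79 to -1.82 for UMAMIT27 (-2.61). At 40 °C with isoprene WRKY50 was above background on no array and NCED5 and UMAMIT27 on 1 of 3, so the sizes of these falls are uncertain. It went from 2.21 to -1.27 for ZAT12 (-3.48), from 2.57 to -0.80 for ZAT10 (-3.37) and from 1.14 to -1.42 for PR5 (-2.56). It turned upwards for TTL4, from -0.58 to 1.25 (1.83), and for CYP83B1, from -0.26 to 0.16 (0.42). UGT76E12 met the same rule, from -0.37 to 4.09 (4.46), but was below background on all arrays at 23 °C, so no direction is shown there. The limma test of the difference gave an adjusted p of 1 for each of the 11, and 6 of them had been named because their p for this difference was among the smallest. Groups of 3 arrays were not searched for single outlying values.

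Probes that match no locus were not part of the comparisons. Of 3256 such probes 1199 changed with heat without isoprene and 1000 with heat and isoprene, and none with isoprene.

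The unfumigated leaf of replicate 1 at 23 °C differs from the other 5 leaves at 23 °C in its clock genes. Its morning gene LHY stands at -2.72 against 3.80 to 4.39, and its evening gene GI at 1.09 against -3.59 to -0.94. Slide or scan session is argued against, since the isoprene array of the same slide moved by a share of -0.009 of the shift. A leaf taken at a later time of day may explain it: all 7 dawn-phased genes measured (CDF1, CDF2, CDF3, CDF5, COL1, COL2 and GBSS1) lay below all 5 others. Of these COL2 is also named above for its fall with heat and isoprene. A swapped label or an altered clock in this plant was not tested and stays open.

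On the array of the unfumigated leaf of replicate 3 at 23 °C some transcripts that are otherwise seen at 40 °C only were bright, HSP21 among them. By number they were not particular to it: of the heat-induced genes below background on the other 5 arrays 12.24% were above background here, against 11.93% for the unfumigated leaf of replicate 1 and 10.68% for the isoprene leaf of replicate 2. A small amount of RNA or label from a heated leaf predicted a slope of its signal on a heated array's near 1. Over the 35 such genes above background the slope was 0.346 (SD around the line 0.975), under the bound set for it, but genes picked for lying above background are truncated at the detection limit, which flattens the slope whatever the source. A further test, run after the first had missed its bound, gave a slope of 1.17 over the 7 brightest heat-only genes, with an SD of 1.48, too wide to decide. For a mild heat response of the leaf itself, 852 heat-induced genes that are also expressed at 23 °C lay at a median of only 0.0738 above the other leaves (interquartile range -0.32 to 0.44), but this set is wide, and the 21 heat shock genes expressed on all 6 arrays lay at a median of 1.11 above them (0.358 to 1.354). The same median ran from -1.954 to 0.3998 for the other 5 leaves. Carry-over and a mild heat response could each be the source, and neither is excluded.

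At 40 °C the isoprene array of replicate 2 and the unfumigated array of replicate 1 stand apart from the other 4. Signal brightness of the array is argued against, since over the brightest genes alone their correlation with the other heated arrays still lay at least 0.0756 below the lowest of the rest. A smaller heat response or a mixture with unheated leaf may explain part of it. The slope of the heat change on that of the other arrays was 0.721 for the isoprene array and 0.747 for the unfumigated array, against 1.03 to 1.08. These 2 were not told apart, and not all changes were smaller: from the mean of the unheated group, the endoplasmic reticulum median of the isoprene array was 1.787 (4.284 and 4.831 for the others with isoprene) but its glucosinolate median -4.268 (-3.936 and -3.226), and the cell wall median of the unfumigated array was -1.177 (-3.04 and -2.364) but its heat shock median 8.887 (8.167 and 8.181). One of the arrays belongs to each isoprene group.

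Splits of the 6 arrays of a comparison number 10, too few for a share under 0.05. At 23 °C the real split gave 181 genes at an unadjusted p under 0.05 and the highest other 913 (6 splits gave as many as the real one), with 6 lists against 10 (7 splits). At 40 °C it gave 684 genes against 5316 (9 splits) and 4 lists against 9 (5 splits). Other splits there passed 1318 and 1001 genes at an adjusted p under 0.05, while the real split passed 0, which points to a structure among the heated arrays other than isoprene. The 1318 came from a split with slide 1 against slide 2 and the 1001 from one with slide 2 against slide 3. Splits that part every pair passed 0. The remaining splits with whole slides on opposite sides also passed 0, so slide alone is not shown to be that structure. For heat without isoprene the real split gave 6704 genes and the highest other 0 (1 split, the real one), with 5 lists against 10 (7 splits). For heat with isoprene it gave 6505 against 0 (1 split), with 9 lists against 14 (7 splits). The number of lists thus did not set the real split apart for heat, where the number of genes did, and it cannot decide for isoprene. The real split parts all 3 pairs of arrays of a slide, as do 3 of the other 9, and the remaining 6 part 1 pair. Among those that part all pairs, the highest other was 97 genes and 10 lists at 23 °C and 1551 genes and 9 lists at 40 °C.

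For the difference between the heat responses, isoprene labels were exchanged within each temperature in 100 relabellings. Of these 93 gave as many genes as the 232 observed at an unadjusted p under 0.05 (highest other 4780), and 69 as many lists as the 4 observed (highest other 13). Most of them keep some slide differences in the contrast, so the 32 that part both arrays of every slide, as the real labels do, were also run. Chance cannot be excluded among these either: 23 gave as many genes (highest other 613) and 25 as many lists (highest other 12). For the correlation of 0.27 between the isoprene effects, 6 of the 100 were as large in size (highest other 0.342). The 6 include the real labels and their mirror, whose correlation is -0.271. Exchanging all labels at one temperature turns only the sign, so some sizes were counted more than once and this share cannot decide. The relabellings that part every slide give 16 different sizes, too few for a share under 0.05, with 0.204 as the highest other (1, the real one, was as large).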

How the results depend on the processing

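Leaving out the arrays that stood apart, joining this or the replicate block with an estimated correlation, and fitting the arrays of one temperature with the replicate block were chosen after the data were seen; the other alternatives were planned. Of 4166 values of the named genes under the alternatives, 4025 kept their side of the threshold, 135 no longer passed and 6 newly passed. Direction was compared only where a gene passed in the main analysis or under the alternative, and 0 of these values changed direction. It was not compared where a gene passed in neither, which holds for nearly all values for isoprene and for the difference. All list calls kept their direction under every alternative. Where a value below changed, the cause was not tested, except that leaving out arrays also removes replicates.

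Genes changed by isoprene went from 0 to 6 at 23 °C with array weights and to 179 at 40 °C without the 2 heated arrays that stood apart. Without those arrays the isoprene and unfumigated groups at 40 °C lie partly on different slides, so slide may enter the 179. Genes changed by heat, 6704 without and 6505 with isoprene, were 3741 and 3114 with normexp, 10820 and 11868 with array weights, and 10372 and 10499 without those 2 arrays; without the 2 unfumigated arrays at 23 °C that stood apart, heat changed 1567, with 1 unheated array left in that group and the spread taken from the others. With the replicate block, which is the slide, the counts were 8388 and 8188. With an estimated correlation 0 lists passed in all 5 contrasts, also with the replicate block or without the arrays that stood apart. With normexp background the lists were 1 for isoprene at 23 °C (6 in the main analysis), 9 for heat without isoprene (5) and 7 for the difference between heat responses (4), and the authors' value table also gave 9 for heat without isoprene. Without the 2 heated arrays that stood apart they were 9 for isoprene at 40 °C (4), with the same limit from the slides. The correlation of the isoprene effects, 0.27, turned to -0.0745 with normexp.

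Leaving out single arrays or whole replicate numbers gave 1604 to 8405 genes for heat without and 1325 to 8364 for heat with isoprene, and 0 for isoprene and for the difference. Lists ranged from 5 to 9 for isoprene at 23 °C, 1 to 10 for isoprene at 40 °C, 5 to 7 for heat without isoprene, 5 to 11 for heat with isoprene and 2 to 9 for the difference. The correlation ranged from 0.135 to 0.279 for isoprene (lowest single array 0.161, the isoprene array of replicate 1 at 40 °C) and from 0.888 to 0.934 for heat. Without replicate 2 of all groups, heat changed 3745 genes without isoprene, and 7 lists passed for isoprene at 40 °C and 9 for the difference; without replicate 1, heat changed 4271 with isoprene.

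Quantile normalization, scaling to probes above background on all arrays, the value table, the filters on dim probes, the plant block, the fits on 1 contrast, the variance trend, the mean of probes, the 2-fold minimum and the threshold of 0.1 kept every total of genes past the threshold within 1.5 times. The stricter filter on dim probes, which tests fewer genes, took the falls with heat from 3423 to 2110 without and from 3542 to 2023 with isoprene. Counts at an unadjusted p under 0.05 moved more: fits on 1 contrast took 181 to 377 at 23 °C and 684 to 310 at 40 °C, the same with the replicate block gave 1316 and 673, the replicate block alone 322 and 1111, array weights 2603 and 3042, and normexp 192 and 218. Left-out arrays gave 57 to 364 and 405 to 2299, and 4198 at 40 °C without the 2 that stood apart. Signal over background limits fold changes of genes dim in one group, given as bounds.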

Other observations

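In this part 15 gene groups defined by symbol were added after the data were seen, without members of the 24 lists, and all tests in it were chosen afterwards. With heat, small auxin-up RNA genes fell in 10 of 15 cases without isoprene and 12 of 15 with it (medians -2.99 and -3.30; camera adjusted p = 0.000346 and 0.000102; adjusted p = 0.336 and 0.33 with an estimated correlation). Type A response regulators, which restrain cytokinin signalling, fell in 5 and 7 of 9 cases (medians -3.14 and -4.51; adjusted p = 0.00382 and 0.00014; 0.336 and 0.238 with an estimated correlation). SPL factors of development fell in 7 of 13 cases in both (medians -2.48 and -2.165; adjusted p = 0.0281 and 0.00773; 0.336 and 0.238 with an estimated correlation). The large falls of SPL2, RR16 and KCS1 had been named before, so groups were tested again without all genes named for their own change or p: the SPL group, without both genes of the symbol SPL2, still passed (0.0312 and 0.00565; 0.336 and 0.253 with an estimated correlation), as did the type A group without ARR15 and RR16 (0.0128 and 0.00251; 0.336 and 0.253). Cellulose synthases fell in 4 of 6 cases in both (medians -2.04 and -1.83; adjusted p = 0.0132 and 0.0427; 0.336 and 0.526 with an estimated correlation). Ketoacyl-CoA synthases passed without isoprene (5 down and 1 up of 16; adjusted p = 0.0375; 0.385 with an estimated correlation) but not without KCS1 (0.0766), and so did heat shock factors outside the list (5 up and 1 down of 9; 0.0437; 0.336) and cyclins with isoprene (7 down and 1 up of 22; 0.0317; 0.526). In all, 6 groups passed in heat without and 5 in heat with isoprene.

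With isoprene at 23 °C all 9 type A response regulators were positive (median 1.05, adjusted p = 2.55e-11; adjusted p = 0.04 with an estimated correlation), and no single gene among them passed. The group was added because ARR15 had been named, so it was tested again without that gene: all 8 others were positive, with a median of 1.02 (adjusted p = 5.74e-08; 0.0551 with an estimated correlation) and 1.24, 2.16 and 0.34 within slides 1, 2 and 3. With single arrays at 23 °C left out, the adjusted p with an estimated correlation ran from 0.0188 to 0.333 for the 9 genes. Cyclins had a positive log2 fold change for 20 of 22 members, none of which passed (median 0.41, adjusted p = 0.0115; 0.825 with an estimated correlation). At 40 °C all 9 phi-class glutathione transferases had a negative log2 fold change with isoprene, none of which passed (median -1.17, adjusted p = 4.9e-08; 0.469 with an estimated correlation), and so were the 7 other than GSTF7 and GSTF2 (median -1.07, adjusted p = 0.00191; 0.665), with -3.27, -0.72 and 0.07 within the slides. A further 4 groups passed at 40 °C: small auxin-up RNA genes (0.0352), WRKY factors (0.0427; 0.109 without WRKY50), cellulose synthases (0.0352) and aquaporins (0.0402), each with an adjusted p of at least 0.665 with an estimated correlation. For the difference between the heat responses 3 groups passed, all more negative with isoprene: phi-class glutathione transferases (adjusted p = 6.2e-07; 0.632 with an estimated correlation), cyclins (0.00872; 0.694) and type A response regulators (0.0149; 0.694). Without the genes that led to these groups being chosen, the type A call ended (0.162) and the phi-class call remained (0.00683; 0.694 with an estimated correlation).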
